A study of Homo sapiens with 2 samples.

How the data were processed

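The data are 2 nanopore direct RNA libraries of HCT116 cells, made with kit SQK-RNA004 from 1 μg of total RNA, per the labels' protocols. A first ligation with custom barcoded adapters, per the same protocols, joined 5 subsamples in each library. Per the deposited barcode table, each sorted level has 3 barcodes that the authors merged and each uninduced subsample has 1, and the same adapters serve the same level in both libraries. The barcodes within a level cannot be separated in the deposited tables, so a level is 1 observation. The transgene is confounded with the library, and the level with its set of barcodes. Uninduced and sorted cells also differ in doxycycline, IAA, sorting and barcodes. A difference between them, called a replacement change here, cannot be credited to replacement alone.

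The deposited tables hold a row per read with its subsample, its poly(A) site and its tail length in nt, per the file headers. The submitters' processing notes name minimap2, Bowtie2 and hg38 with no version or role. The basecaller, the caller of tail lengths and the demultiplexer are not given in the sources used here. Tail lengths of exactly 0 were kept in the main analysis. Reads of a sample name that the barcode table does not list (2.86% of the PABPC1 library and 5.63% of the PABP1212 library) entered no comparison. The spike sequences in the barcode table were not used here.

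Positions of the sites were compared with the GENCODE v29 annotation of hg38. Of 9004 sites, 240 (2.67%) lay within 25 nt of a transcript end, and the last site on chromosome 8, at 146281416, lay beyond the last transcript end there, at 145066685. The sites are therefore on coordinates other than hg38, no gene name was taken from them, and no position was converted. The poly(A) site, listed beforehand as a second choice to the gene, became the unit. Gene lists, the naming of PABPC1 and PABPC4 transcripts, the use of alternative sites within a gene and settings without mitochondrial or ribosomal protein genes were not analysed here. No site lay on the mitochondrial chromosome, and 1699 sites lay under 500 nt from the previous site on their strand, so neighbours can belong to the same gene.

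Depth ranged from 65862 to 630986 reads per subsample. Tail length per subsample was the median over sites, with at least 10 reads, of the site's median, with a 95% bootstrap interval over sites (1000 resamples). Shares of reads with tails under 30 nt and of at least 150 nt have exact Clopper-Pearson 95% intervals. Trends over the 4 levels were tested by two-sided exact permutation of the levels, within each library (24 orders) and jointly (576 orders). The joint test permutes each library independently and does not account for the adapters that the libraries share at each level. Within-site changes used the 914 sites with at least 10 reads in all 10 subsamples.

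Per-site tests used limma 3.58.1 in R 4.3.3, with library, replacement within library and centred level rank within library as terms, which leaves 4 residual degrees of freedom. The spread is that around a straight line over the levels, which may be technical, and each lone uninduced subsample is assumed to vary like the others. Tail length entered as the mean of log2(nt + 1) per site, weighted by reads. Abundance was counted here from the reads, as log2(CPM + 1) after scaling by the median ratio to the geometric mean over 5662 sites, for sites with a mean of 10 reads, with a variance trend. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Other analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

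The fits were tested on simulated data made from the read numbers and means of these subsamples, with 200 sites changed. For the PABP1212 tail trend over 914 sites, 46% of changes of 0.2 log2 per level and 99.5% of changes of 0.5 were recovered, and for the PABPC1 tail trend 22% and 71%. For the tail replacement change, 8% (PABPC1) and 42.5% (PABP1212) of changes of 0.5 log2 were recovered. In coefficients with nothing changed, the tail fit called at most 1 site. For abundance, the simulated reads were Poisson counts with a log-normal spread of a fixed size that was not estimated from these data. The simulated noise was independent between sites, for tails and for abundance. A shift shared by all sites of a subsample was therefore not covered, and the simulations give no false call rate for it. The abundance fit with a mean of 10 reads called up to 132 sites (median 115) for the PABPC1 replacement change, up to 38 for the PABPC1 trend and up to 56 for the replacement difference, while with a mean of 50 reads these were at most 4, 2 and 0. Where PABPC1 trends were simulated, the fit with a mean of 50 reads also called unchanged sites, 10 beside 26 changed ones at 0.5 log2 per level and 12 beside 37 at 1 log2. For PABPC1 replacement changes of 1 log2 it called 7 unchanged sites beside 14 changed ones. The abundance results therefore lead with a mean of 50 reads (801 sites), a filter listed beforehand as a second setting. Giving it the lead was a choice made after that simulation and after the data were examined, and the counts with a mean of 10 reads stand beside them. With a mean of 50 reads, 53.1% of PABPC1 trends and 28.9% of PABP1212 trends of 0.5 log2 per level were recovered.

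The tests, thresholds and most alternatives were fixed before the data were examined. Alternatives covered the read minimum, the summary and scale of tail length, weights, thinning of every subsample to 65862 reads, tails under 10 nt, scaling, pseudocount, filters, voom weights, each library alone and each subsample left out. The rule for named sites took those past the threshold with at least 20 reads in every subsample and the largest change, limited to 2 that fell and 2 that rose because the files do not pair sites with genes. It had allowed up to 6 per direction. A fit of the highest against the lowest level alone leaves no residual degrees of freedom and was not run.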

Results

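Poly(A) tail lengths were measured by nanopore direct RNA sequencing, which reads native RNA molecules, in HCT116 cells, a human colon cancer line. Both cytoplasmic poly(A)-binding proteins PABPC1 and PABPC4, which coat the tails of mRNAs, carried a degron tag that allows their removal on addition of indole-3-acetic acid (IAA, an auxin). Cells were treated for 13 days with 1 μg/mL doxycycline and 0.5 mM IAA, so that a transgene took the place of the tagged proteins. The transgene was either PABPC1 or PABP1212, a PABPC1 in which RRM1 and RRM2, domains of the RNA-binding part of the protein, were duplicated. Treated cells were sorted into 4 gates of 25% of the cells each by expression of the transgene, and an untreated, unsorted subsample was sequenced alongside. There were 2 libraries, 1 per transgene, each with 5 barcoded subsamples, and no subsample was repeated within a library. The subsamples are named here uninduced, lowest level, second-lowest level, second-highest level and highest level.

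In the PABPC1 library, in that order, 67552, 65862, 102256, 193416 and 104787 reads had a tail length. In the PABP1212 library the numbers of reads were 210926, 139869, 303281, 630986 and 578987. The numbers of poly(A) sites with at least 10 reads ranged from 1286 in the PABPC1 uninduced subsample to 6907 in the PABP1212 second-highest level, and 914 sites had at least 10 reads in all 10 subsamples. The files do not pair sites with gene names, so sites were described as groups and a few by position.

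The series addresses how tail length responds to replacement of the cellular proteins by either transgene at graded expression. Tails were longest at the lowest level of either transgene and shorter at higher levels. With PABPC1, the median over sites of the site's median tail was 118 nt at the lowest level (95% bootstrap interval over sites, 117 to 119.5), 106 nt (104 to 107) at the second-lowest level, 103 nt (102.5 to 104) at the second-highest level and 101 nt (100 to 102) at the highest level, against 97 nt (96 to 98) in uninduced cells. With PABP1212 it was 127 nt (125.5 to 128), 103 nt (102 to 104), 88 nt (87 to 88) and 89.5 nt (89 to 90), against 99 nt (98 to 99.5) in uninduced cells. In these medians, each over the subsample's own sites, PABPC1 levels all lay above uninduced, while the upper levels of PABP1212 lay below. Over the 914 sites measured in every subsample the PABPC1 medians were 116.5, 103, 99 and 99.5 nt, against 96 nt in uninduced cells. The slope was −5.45 nt per level with PABPC1 (two-sided exact permutation p = 0.0833, the smallest that 24 orders of the levels allow) and −12.75 nt per level with PABP1212 (exact p = 0.167), so that neither library could pass 0.05 alone. A joint exact permutation of both libraries over 576 orders gave p = 0.00694. Over the 914 shared sites the slopes were −5.5 and −13.25 nt per level (exact permutation p = 0.167 in each library), and the joint exact permutation gave p = 0.0139. The joint test permutes each library independently, although the same adapters serve the same level in both. Orders common to both libraries would number 24, too few to pass 0.05. Without the PABP1212 lowest level the joint exact p was 0.0556. Without its own lowest level the slope was −2.5 nt per level with PABPC1 and −6.75 with PABP1212, and without its highest level −19.5 with PABP1212. The slope difference of −7.3 nt per level between the libraries did not pass an exact permutation test (p = 0.25, where 0.125 was the smallest possible).

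**Figure D1:**
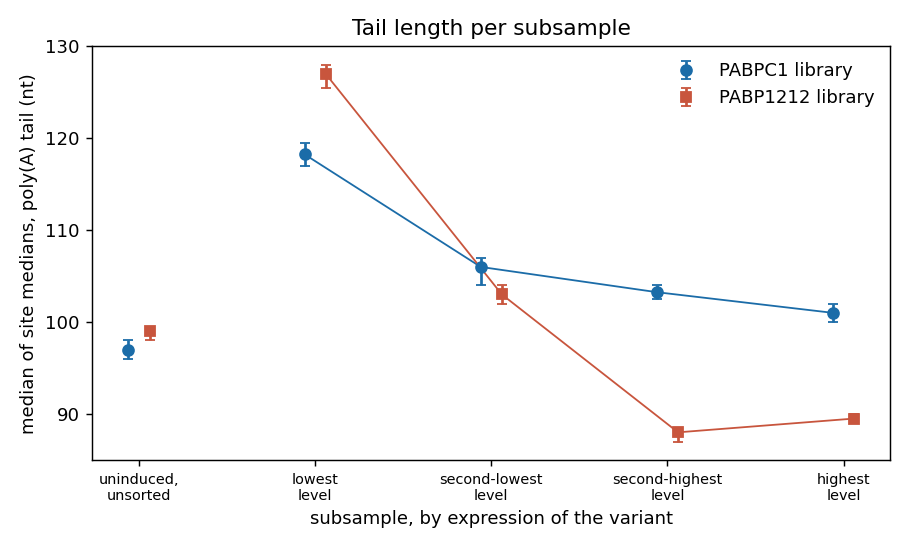
Median of the site medians of poly(A) tail length (nt, vertical axis, not starting at 0) in each subsample of the PABPC1 library (circles) and the PABP1212 library (squares), with 95% bootstrap intervals over sites as bars and lines joining the sorted levels. The lowest levels stood highest, at 118 and 127 nt, and the PABP1212 library ended at 89.5 nt, below its uninduced 99 nt.

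Both ends of the tail length distribution moved with the level of the transgene. Short tails, under 30 nt, made up 3.94% of reads (Clopper-Pearson 95% interval 3.79 to 4.09) at the lowest PABPC1 level and 6.87% (6.72 to 7.02) at the highest, against 5.26% (5.09 to 5.43) in uninduced cells. With PABP1212 they made up 7.88% (7.74 to 8.02) at the lowest level, 14.3% (14.2 to 14.3) at the second-highest and 13.2% (13.1 to 13.3) at the highest, all above the uninduced 6.21% (6.11 to 6.32). Long tails, of 150 nt or more, made up 30.4%, 22.6%, 21.3% and 22.4% of reads from the lowest to the highest PABPC1 level, and 38.9%, 26.9%, 19.2% and 18.3% with PABP1212, against 19.1% and 17.7% in the uninduced subsamples of these libraries. The PABPC1 slope of −2.54 percentage points per level was −0.10 without the lowest level and −4.56 without the highest, and the PABP1212 slope of −6.96 was −4.30 without its lowest level and −9.86 without its highest. The joint exact permutation test, again with each library permuted independently, gave p = 0.0208 for short tails and p = 0.0139 for long tails. The exact p for short tails was 0.0556 without the PABPC1 lowest level, 0.111 without the PABP1212 lowest level and 0.0694 for tails under 20 nt, and that for long tails was 0.0694 without the PABPC1 lowest level. The intervals cover counting error only.

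The same sites carried longer tails at the lowest levels than in uninduced cells. Over the 914 sites measured in every subsample, the median change from uninduced at the lowest level was +20 nt (95% bootstrap interval 19 to 21.5) with PABPC1, where 750 sites were longer and 158 shorter. With PABP1212 it was +25.8 nt (24 to 27), with 832 sites longer and 79 shorter. At the highest level the change was +3 nt (1 to 4.01) with PABPC1 and −13.2 nt (−14.5 to −12.5) with PABP1212, where 766 of the 914 sites were shorter. The second-highest PABP1212 level was alike, at −15 nt (−16 to −14), while the PABPC1 interval at that level included 0 (+1 nt, −0.5 to 2). At the second-lowest level the changes were +7 nt (5.5 to 8) and +1 nt (0.5 to 2). The change with PABP1212 minus that with PABPC1 was +6.5 nt (4 to 8.5) at the lowest level and −17 nt (−18 to −15) at the highest. Each such value compares individual subsamples and has no replicate check, and the intervals cover the sampling of sites and reads only.

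**Figure D2:**
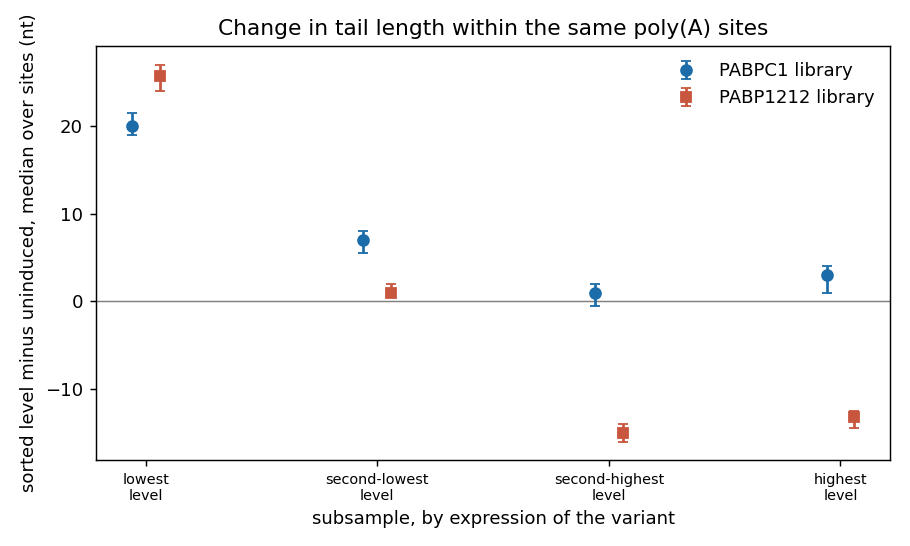
Median over the 914 shared sites of the tail length at each sorted level minus that in the uninduced subsample of the same library (nt), with 95% bootstrap intervals over sites as bars, for the PABPC1 library (circles) and the PABP1212 library (squares). Both libraries stood above 0 at the lowest level, and the PABP1212 library stood at −15 and −13.2 nt in the upper levels.

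Tail shortening with rising PABP1212 was spread over nearly all sites. When the 914 sites were grouped by their tail in the uninduced subsample of the other library, the median slopes with PABP1212 were −13.2, −13.5 and −13.5 nt per level from the shortest to the longest group. With PABPC1 they were −6.45, −5.03 and −4.8 nt per level. On the log2 scale, the Spearman rho across the 914 sites between the trend and that uninduced tail was 0.19 with PABP1212 and 0.13 with PABPC1, so sites with shorter tails had the steeper relative trends. In a limma fit of log2 tail length over both libraries, 139 of the 914 sites had a PABP1212 trend past a Benjamini-Hochberg adjusted p of 0.05, all toward shorter tails at higher levels, and the median trend over sites was −0.14 log2 per level (−0.27 without the PABP1212 highest level). All sites share the same subsamples, so these calls are not independent of each other. With subsample medians subtracted, which removes a shift shared by all sites, 6 of the 139 calls were kept. In that setting 10 sites passed, 4 longer and 6 shorter relative to the other sites. For PABPC1 the median trend was −0.08 log2 per level (−0.03 without its lowest level and −0.14 without its highest), and 0 sites passed in limma (15 at an unadjusted p under 0.05, and 6 adjusted calls without weights). The unadjusted PABPC1 count was 104 and 106 without the PABP1212 second-highest and highest levels, and 129 with each library fitted alone. Without the PABPC1 lowest level it was 0. The difference of the trends between the libraries passed at 0 sites (2 at an unadjusted p under 0.05), and at 139 sites, all lower with PABP1212, without the PABP1212 highest level. The count of 139 changed more than the trend when a subsample was left out. It was 11 without the PABP1212 lowest level, where the median trend was −0.10 log2 per level and 12.7% of sites had a positive trend, and 13 without its second-lowest level, where these were −0.12 and 7.33%, against 3.17% with all subsamples. It was 490 without its second-highest level, 665 without its highest level and 71 without the PABPC1 highest level. Of the 12 distinct orders of the PABP1212 levels, 2 gave at least 139 calls, the real order included, which is too few orders for a share under 0.05.

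The change between uninduced cells and the mean of the sorted levels passed at 0 of the 914 sites for either transgene in the same limma fit, with 1 site for PABPC1 and 34 for PABP1212 at an unadjusted p under 0.05. The median change over sites was +0.04 log2 with PABPC1 and −0.12 log2 with PABP1212. For PABPC1 it was +0.01 without the lowest or the highest level and +0.09 without the second-highest, and for PABP1212 −0.04 without its second-highest level. For PABP1212 it joins levels that lay above and below uninduced. Without a log the PABP1212 median was +2.64 nt, so its direction depends on the scale. Without tails under 10 nt it was −0.05 log2, so its size also depends on the shortest tails. The PABP1212 count was 66 without the PABP1212 highest level. The difference between the transgenes passed at 0 sites (2 at an unadjusted p under 0.05). Because uninduced and sorted cells also differ in doxycycline, IAA, sorting and barcodes, these changes cannot be credited to the transgene alone.

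The lowest PABP1212 level had the widest range of tails within a site in nt, though not relative to tail length. The median over the 914 sites of the interquartile range of tail lengths within a site was 110.5 nt there (95% bootstrap interval 109 to 112), against 72 nt in the uninduced subsample and 74 nt at the lowest PABPC1 level. Divided by the median tail it was 0.923, 0.999, 1.07 and 1.01 from the lowest to the highest PABP1212 level and 0.774 in uninduced cells. At the sites named here, positions are those of the files, on a build not given in the sources used here. A site on chromosome 14 at position 58738722 of the plus strand had median tails with PABP1212 of 125, 86, 68 and 67 nt from the lowest to the highest level and 95 nt in uninduced cells, a trend of −0.28 ± 0.08 log2 per level (SE; limma adjusted p = 0.0179). A site on chromosome 12 at position 3320759 of the minus strand had 97.5, 64, 44 and 39 nt and 75 nt uninduced, a trend of −0.28 ± 0.04 (SE; limma adjusted p = 0.000454). Their PABPC1 trends, −0.06 and −0.11 log2 per level, did not pass (limma adjusted p = 0.995 for both). The PABP1212 call of the chromosome 14 site was lost under 6 alternatives and kept under 15, and that of the chromosome 12 site was kept under all 21.

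Relative abundance changed with the level of the transgene in both libraries, with the largest median changes among the most abundant sites. Among the 801 sites with a mean of 50 reads, 104 had an abundance trend with PABPC1 (80 higher and 24 lower at higher levels) and 178 with PABP1212 (152 higher and 26 lower) at a limma adjusted p under 0.05. Of these, 34 sites rose in both libraries and 12 fell in both, where independent lists would share 15.2 and 0.779. The lists are not independent, since the fit gives a site the same residual variance in both libraries and the levels share barcode sets. The excess is therefore no test of a shared response. The trend difference between the libraries passed at 0 sites in limma (53 at an unadjusted p under 0.05). Across the 801 sites, which are not independent replicates, the trends of the libraries had a Spearman rho of 0.61. Scaled by total reads, the PABPC1 trends were 55 higher and 31 lower and the PABP1212 trends 84 higher and 30 lower. With voom precision weights there were 26 PABPC1 trends (16 higher and 10 lower) and 191 PABP1212 trends (160 higher and 31 lower). The lowest levels carried much of this: 4 sites passed without the PABPC1 lowest level, and 1 site passed for PABP1212 without its lowest level. For PABPC1 the count was also 239 without its second-lowest level, 19 without its second-highest level, 6 without its highest level and 58 without the PABP1212 second-highest level. For PABP1212 it was 105 without the PABPC1 second-highest level and 111 without the PABP1212 second-highest level.

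At the lowest level, the 267 sites with the most reads were lower relative to the others than in uninduced cells. Grouped by reads in the uninduced subsample of the other library, their median change was −0.57 log2 (95% bootstrap interval −0.63 to −0.51) with PABPC1 and −0.76 log2 (−0.85 to −0.67) with PABP1212. The 267 sites with the fewest reads of the 801 changed by −0.01 log2 (−0.14 to 0.11) and −0.09 log2 (−0.20 to −0.01). Both the grouping and the baseline of this change are uninduced subsamples, of different libraries but of the same untreated state. Sites grouped as high in that state can therefore fall in any other, and this change is not separate from the grouping. The slopes over the 4 levels use no uninduced baseline. Across the 4 levels, the median slope of the sites with the most reads was 0.10 log2 per level (0.08 to 0.13) with PABPC1 and 0.16 (0.15 to 0.19) with PABP1212, and that of the sites with the fewest was 0.05 (0.02 to 0.08) and 0.04 (0.02 to 0.06). These are shares of each subsample's reads on the log2(CPM + 1) scale and say nothing of total mRNA.

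**Figure D3:**
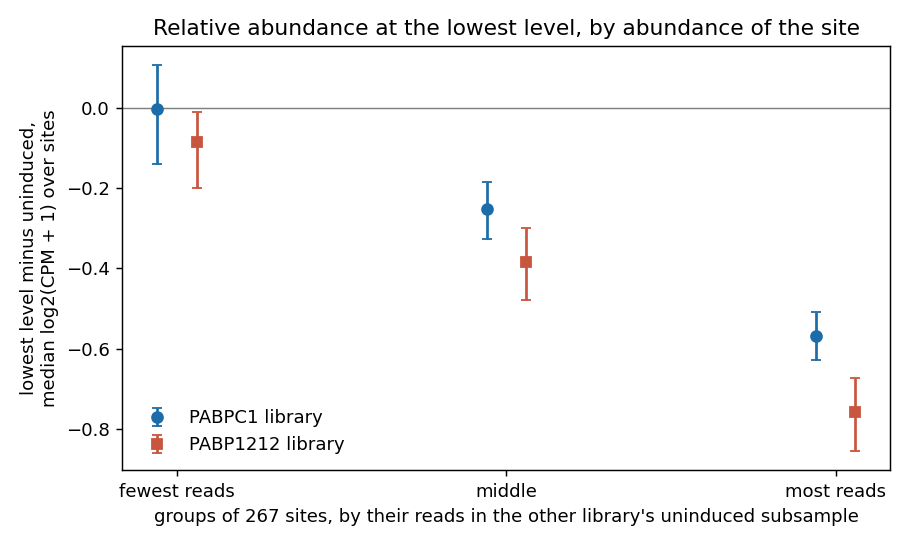
Median over sites of the log2(CPM + 1) at the lowest level minus that in the uninduced subsample of the same library, for 3 groups of 267 sites ordered by reads in the uninduced subsample of the other library, with 95% bootstrap intervals over sites as bars, for the PABPC1 library (circles) and the PABP1212 library (squares). The sites with the most reads stood at −0.57 and −0.76.

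Between uninduced cells and the mean of the sorted levels, 201 of the 801 sites differed in abundance with PABPC1 (79 higher and 122 lower) and 100 with PABP1212 (16 higher and 84 lower), by limma with adjusted p under 0.05. The difference between the transgenes passed at 5 sites, all lower with PABP1212 relative to PABPC1. With voom precision weights the counts of 201 and 100 became 112 (42 higher and 70 lower) and 168 (15 higher and 153 lower). The sizes of the counts therefore do not rank the transgenes. Scaling by total reads turned the PABPC1 split to 114 higher and 105 lower and gave 24 higher and 26 lower with PABP1212. That scaling moved the median PABP1212 change over the 801 sites from −0.21 to −0.04 log2, and over the 4277 sites with a mean of 10 reads from −0.03 to +0.14 log2, so directions of single sites are relative to the scaling. Leaving out the PABPC1 highest level also turned the PABPC1 split, to 74 higher and 69 lower. The PABP1212 count was 197 without the PABPC1 lowest level, 168 without its second-lowest level, 36 without its second-highest level, 50 without the PABP1212 lowest level and 62 without its highest level. The 5 sites became 24 without the PABPC1 lowest level, 8 without the PABP1212 second-lowest level, 3 without its second-highest or highest level and 0 without the PABPC1 second-highest or the PABP1212 lowest level.

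The filter chosen before the data were examined, a mean of 10 reads, took in 4277 sites. It gave 91 sites with a PABPC1 trend (52 higher and 39 lower) and 8 with a PABP1212 trend (5 and 3). The replacement change, sorted against uninduced cells, passed at 551 sites with PABPC1 (395 and 156) and at 41 with PABP1212 (24 and 17). It differed between the transgenes at 97 sites, and the trend at 0 sites in limma (331 at an unadjusted p under 0.05). With voom precision weights the trends numbered 30 and 210 and the replacement changes 159 and 191. With each library fitted alone the trends numbered 13 and 248 and the replacement changes 303 and 254. The sizes of the counts therefore do not rank the transgenes here either. In simulations that left the coefficient in question unchanged and changed sites in another, the fit with a mean of 10 reads also made calls. It called a median of 115 sites (at most 132) for the PABPC1 replacement change, 35 (at most 56) for the replacement difference and 3 (at most 38) for the PABPC1 trend. For the trend difference and the PABP1212 trend and replacement change it called 0 in every simulation. Leaving out a subsample changed these counts. The trend difference passed at 44 sites without the PABPC1 second-lowest level, 4 higher and 40 lower with PABP1212 relative to PABPC1. The 97 sites were 250 without the PABPC1 lowest level, 201 without its second-lowest level, and 47, 44 and 46 without the PABP1212 lowest, second-highest and highest levels. The 91 PABPC1 trends were 657, 26 and 44 without its own second-lowest, second-highest and highest levels, and 3, 2, 16 and 20 without the PABP1212 lowest to highest levels, and without the PABPC1 lowest level (114, 53 higher) or its second-highest level (1 of 26 higher) more were lower than higher. The 8 PABP1212 trends were 150, 94, 0 and 4 without the PABPC1 lowest to highest levels, and 0 and 5 without the PABP1212 lowest and second-highest levels. The 551 PABPC1 replacement changes were 910 and 955 without the PABPC1 lowest and second-lowest levels and 310 without the PABP1212 second-highest level, and the 41 PABP1212 replacement changes were 149, 111 and 12 without the PABPC1 lowest, second-lowest and second-highest levels and 18, 19, 20 and 16 without the PABP1212 lowest to highest levels. In the fit with all subsamples a site on chromosome 15 at position 40328242 of the minus strand rose with the PABPC1 level, from 306 to 845 scaled CPM between the lowest and the highest level, by 0.48 ± 0.09 log2 per level (SE; limma adjusted p = 0.0444). A site on chromosome 1 at position 26227009 of the minus strand rose from 361 to 931 scaled CPM, by 0.44 ± 0.10 (SE; limma adjusted p = 0.0488). With PABP1212 their trends were 0.24 and 0.43 log2 per level (limma adjusted p = 0.273 and 0.0771). The PABPC1 call was lost under 11 alternatives and kept under 21 at the chromosome 15 site, and lost under 16 and kept under 16 at the chromosome 1 site.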

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

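The tests of explanations in this part were chosen after the results were seen.

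Abundance changes between uninduced and sorted cells differed between the transgenes at 97 sites in the limma fit with a mean of 10 reads, which is a difference between groups. In simulations that left this difference unchanged and changed sites in another coefficient, that fit called a median of 35 sites (at most 56) for it. The 97 sites were 250 and 201 without the PABPC1 lowest and second-lowest levels, and 47, 44 and 46 without the PABP1212 lowest, second-highest and highest levels. More sites were higher than lower with PABPC1 replacement in that fit, 395 against 156. Among sites with a mean of 50 reads, 79 were higher and 122 lower, and 5 sites differed between the transgenes. Few reads in the PABPC1 uninduced subsample predict no excess of higher sites with a mean of 50 reads, and the split there depended on the setting. It was 114 higher and 105 lower with scaling by total reads, and 74 and 69 without the PABPC1 highest level. With a mean of 10 reads and every subsample thinned to the same number, 44 were higher and 31 lower. Few reads and a change of abundance therefore cannot be told apart as the source of the excess. In simulations that left the PABPC1 replacement change unchanged, the fit with 10 reads also called a median of 115 sites for it.

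Reads of the sample name that the barcode table does not list had tails of exactly 0 more often than the named subsamples, a signal outside the compared data. They made up 9.69% of such reads (Clopper-Pearson 95% interval 9.23 to 10.2) in the PABPC1 library and 23.6% (23.3 to 23.8) in the PABP1212 library, where the highest values of a named subsample were 1.18% and 2.25%.

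Tails were longer at the lowest level and fell toward the highest. The sampling of different sites is argued against by the change of 20 nt within the same sites with PABPC1, and failed estimates by the PABP1212 slope of −12.9 nt per level without tails under 10 nt. The barcode set of each level and the expression of the transgene cannot be told apart, because each level has the same set in both libraries, and this covers the 25.8 nt with PABP1212 at the lowest level. The difference between the libraries does not settle this, as the exact permutation test of the slope difference (p = 0.25) cannot go below 0.125 with 4 levels. The 12 distinct orders of the 4 PABP1212 levels are too few for a share under 0.05, and 2 of them gave at least the 139 tail trends seen. The other order, with 563, exchanged the second-highest and highest levels, whose median tails were 88 and 89.5 nt. The count therefore does not single out the real order, and the reason for the larger count was not tested.

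The most abundant sites were relatively lower at the lowest level than at the highest. Unequal numbers of reads are argued against, since with every subsample thinned to 65862 reads the slope of the sites with the most reads still exceeded that of the sites with the fewest by 0.141 log2 per level (95% bootstrap interval 0.100 to 0.187) with PABP1212 and by 0.057 (0.025 to 0.104) with PABPC1. The barcode set cannot be told apart from the expression of the transgene, again because the sets are shared. The 12 distinct orders of a library's levels are too few for a share under 0.05, and 1 of the 12, the real order, gave as many abundance trends with a mean of 50 reads for PABPC1 (104, highest other 10) and for PABP1212 (178, highest other 103). With a mean of 10 reads it was also 1 of the 12 for PABPC1 (91, highest other 1) and for PABP1212 (8, highest other 0).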

How the results depend on the processing

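Settings with both lowest or both second-highest levels left out, with subsample medians subtracted, with tails of 0 left out, and those that join a mean of 50 reads with a further change were chosen after the data were examined. Of the values under the alternatives, named sites included, 416 stayed on their side of the threshold and within the limits set for a change, 131 moved beyond them, 38 lost their call and 15 reversed. The tail slopes and the median tail trends over sites kept their direction under every alternative run, leaving aside subtracted medians, which remove them. Unless a cause is named, the cause was not tested.

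The median tail per subsample, from uninduced to the highest level, was 95, 117, 103, 98 and 98 nt over all reads with PABPC1 and 92, 123, 96, 79 and 80 nt with PABP1212. At sites with at least 50 reads it was 90, 110.2, 100, 97 and 95 nt, and 93.5, 120, 98, 84.5 and 85 nt. Without tails under 10 nt it was 97.5, 119, 106, 104.5 and 102 nt, and 99, 129.5, 104.5, 91 and 91 nt. Leaving out each subsample gave a PABPC1 slope of −7.5 to −2.5 nt per level, a PABP1212 slope of −19.5 to −6.75 and a joint exact permutation p from 0.0139 to 0.0556. For short tails the joint exact permutation p was 0.0694 under 20 nt, 0.00347 without tails of 0 and 0.0139 to 0.111 with a subsample left out. For long tails it was 0.0139 to 0.0694 with a subsample left out. Fewer orders are possible without a subsample, which raises the smallest p.

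The limma count of PABP1212 tail trends, 139, was 276 with the site's median, 407 in nt without a log, 231 without weights, 427 without tails under 10 nt, 85 with each library alone, 472 without both second-highest levels, 21 without both lowest levels, 10 with subsample medians subtracted (4 longer, 6 shorter) and 11 to 665 with a subsample left out. For PABPC1 it was 6 without weights and 0 to 2 with a subsample left out. The tail replacement count was 4 for PABPC1 without weights. For PABP1212 it was 2 without both lowest levels, 2 with subsample medians subtracted and 0 to 66 with a subsample left out. The PABP1212 median replacement change was +2.64 nt without a log. The trend difference counted 0 to 139 with a subsample left out, and the replacement difference 1 without weights.

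With a mean of 10 reads, scaling by total reads gave 74 PABPC1 abundance trends (30 higher, 44 lower). With log2(CPM + 10) there were 39 PABP1212 trends and 27 replacement differences. With no filter the counts were 2 and 3 for the PABPC1 and PABP1212 trends, 1039 and 18 for their replacement changes and 174 for the replacement difference. With a mean of 50 reads they were 178 for the PABP1212 trend, 201 (79 higher, 122 lower) and 100 (16 higher, 84 lower) for the replacement changes and 5 for the replacement difference, on fewer sites. With voom weights the trends were 30 and 210, the replacement changes 159 and 191 (31 higher, 160 lower) and the replacement difference 2. Thinned to equal reads, which leaves 1170 sites, they were 23 and 95, 75 and 58 (21 higher, 37 lower), and 3. With each library alone the trends were 13 and 248 and the replacement changes 303 and 254. Without both second-highest levels the trends were 4 (1 higher, 3 lower) and 0, the replacement changes 151 and 4 and the replacement difference 0. Without both lowest levels they were 1 and 0, 951 and 125 (52 higher, 73 lower), and 160. With a subsample left out the trends ranged from 2 to 657 and from 0 to 150, the replacement changes from 310 to 955 and from 12 to 149, the trend difference from 0 to 44 and the replacement difference from 44 to 250. The PABPC1 trend turned to more lower than higher sites without the PABPC1 lowest level (114, 53 higher) or its second-highest level (26, 1 higher), and the PABP1212 trend without the PABPC1 highest level (4, 1 higher) or the PABP1212 second-highest level (5, 2 higher).

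With a mean of 50 reads, scaling by total reads gave 114 PABP1212 trends (84 higher, 30 lower), 219 PABPC1 replacement changes (114 higher, 105 lower) and 50 PABP1212 replacement changes. Without both lowest levels the trends were 43 and 16, the replacement changes 389 and 227 and the replacement difference 60. With voom weights there were 26 PABPC1 trends and 112 and 168 replacement changes. With a subsample left out the trends ranged from 4 to 239 and from 1 to 263, the replacement changes from 143 (74 higher, 69 lower) to 285 and from 36 to 197, the trend difference from 0 to 4 and the replacement difference from 0 to 24. Scaling by total reads moved the median PABP1212 replacement change over sites from −0.03 to +0.14 log2 with a mean of 10 reads.

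The only paired test was that of the slope difference, which swaps the libraries within each level (exact permutation p = 0.25). The highest against the lowest level, gene lists, site use within genes and settings without mitochondrial or ribosomal protein genes were not run, and leaving out an uninduced subsample gives no replacement change. Depth limits the PABPC1 library most, where the smallest subsample has 65862 reads.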

Other observations

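The tests in this part were chosen after the results were seen. The autocorrelation of tail lengths and the relation of tail to abundance change were fixed before the data were examined, as descriptions without a test. The simulated p of the autocorrelation was added later.

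Sites with short tails in uninduced cells had higher abundance slopes over the levels of the transgene than sites with long tails. Grouped by tail length in the uninduced subsample of the other library, 3 groups of 267 sites with a mean of 50 reads had median abundance slopes of 0.09, 0.10 and 0.03 log2 per level with PABPC1, from the group with the shortest to that with the longest tails. With PABP1212 the slopes were 0.15, 0.14 and 0.05 log2 per level, in groups of 256, 256 and 257 sites with at least 10 reads in the PABPC1 uninduced subsample. Sites with more reads, which also had higher abundance slopes, had shorter uninduced tails. Over the 914 sites, grouped from the fewest to the most reads, these were 101, 98 and 92 nt in the PABPC1 library. In the PABP1212 library they were 99, 96 and 91 nt, so the relation to tail length was not separated from that to abundance. Over the 914 sites the Spearman rho of the tail trend and the abundance trend was −0.02 with PABPC1 and −0.03 with PABP1212, and that of the replacement changes was −0.01 and 0.12, across sites that are not independent replicates.

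The Spearman rho between the libraries across 914 sites was 0.13 for tail trends, with the same sign at 81.5% of sites, and 4 of 24 orders of the levels gave a value as high. Across 801 sites it was 0.61 for abundance trends, with the same sign at 75.8% of sites, where the real order was the highest of 24 and the next gave 0.59.

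At spacings of 20 to 40 nt, the highest autocorrelation was 0.152, 0.153, 0.359 and 0.189 from the lowest to the highest PABP1212 level. These lay at 31, 27, 26 and 25 nt, and none passed (simulated adjusted p from 0.218 to 0.762). The PABP1212 uninduced subsample and the PABPC1 second-lowest and second-highest levels passed, with 0.180, 0.235 and 0.098. Their highest values lay at 40 nt, the edge of the spacings searched. The simulated 95th percentiles were 0.229 to 0.458 in the sorted PABP1212 levels and −0.064 to 0.025 in the subsamples that passed. Values of similar size thus passed in some subsamples only, so the test does not show that steps were absent.

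The share of tails of exactly 0 followed the same order over the subsamples in both libraries, an outcome that 1 of 120 orders gives. That order did not rise or fall steadily with the level of the transgene. The same adapters serve the same level in both libraries, so adapter and level cannot be told apart for it, as for the tail trend. In the PABPC1 library, from uninduced to the highest level, it was 0.278%, 0.793%, 0.368%, 1.18% and 0.473% of reads, and in the PABP1212 library 0.604%, 2.00%, 0.754%, 2.25% and 0.917%.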
